A study of Drosophila melanogaster with 4 samples.

How the data were processed

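RNA of dvpdf neurons from Drosophila melanogaster brains was measured in 4 libraries, 2 labelled control and 2 labelled NonA RNAi. Per the labels' protocols, mRNA was extracted and amplified by published procedures and libraries were made with Illumina TruSeq kits. The submitters' processing notes name TopHat2 2.1.1, Cufflinks without a version, and genome build dm3; which program counted the reads, the annotation and the use of strand are not given in the sources used here. Per the file headers, each deposited file holds the raw read count of 14163 gene symbols, the length and the RPM and RPKM. The raw counts as deposited were whole numbers with a different total in each library. The RPKM as deposited by the authors was the RPM per kilobase of the listed length. For genes with 1000 or more reads, reads divided by RPM equalled the sum of gene, featureless and ambiguous reads within 0.013%. For 71.3% of 10423 genes the listed length lay within 10 bases of the whole gene span in RefSeq, so RPKM understates genes with long introns. For 559 genes the length, and with it the RPKM, is listed at 0, and 295 of these had reads.

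The 3 entries that name no gene were left out of library sizes and tests. Reads without a feature made up 29.9% and 27.8% of all entries in control replicates 1 and 2 and 32.5% and 29.6% in NonA RNAi replicates 1 and 2. Reads aligned to several places made up 53.9%, 55.6%, 45.2% and 53.7%, ambiguous reads 0.22%, 0.3%, 0.32% and 0.22%, and gene reads 15.9%, 16.3%, 22.0% and 16.5%, with exact (Clopper-Pearson) 95% binomial half-widths for the gene share of at most 0.012 percentage points. Gene reads came to 8419248 and 9832771 in the controls and 9673275 and 8558125 in the NonA RNAi libraries. Because reads with several places were kept apart, members of near-identical gene families are uncertain.

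Genes were kept at a mean RPKM of at least 1 over the 4 libraries, and genes without a length at a mean of 1 CPM, which left 7248 genes, 188 of them without a length. The groups were compared with edgeR 4.0.16 (R 4.3.3), with TMM scaling and the two-sided quasi-likelihood test, and Benjamini-Hochberg adjustment at a threshold of 0.05. CPM are TMM-normalised. Standard errors are the absolute log2 fold divided by the square root of the F statistic. The common dispersion was 0.35, a biological coefficient of variation of 59.1%, with 4.08 prior degrees of freedom. A test on log2 values had been laid down for normalised values, with this count test named for the case that the files held counts, which they did. The alternatives laid down for pseudocounts (0.1 and 5) and quantile normalization were therefore run with limma 3.58.1 on the deposited RPKM, with a pseudocount of 1 for quantile normalization.

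The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took nonA, cpx, Pdf and the core clock genes. In each direction it then took the 10 genes with the largest log2 fold among those past the threshold. Both NonA RNAi libraries had to lie beyond both controls, with a mean of at least 10 RPKM in the higher group. Where fewer passed, genes were filled up by smallest unadjusted p under the same conditions. The rule also took up to 4 genes of each list by smallest unadjusted p. Lists that passed camera gave 4 genes and other lists fewer, so this number depended on the result. The 17 lists were tested with camera with a preset correlation of 0.01, with camera with an estimated correlation, and with fry, where at least 5 members were measured, with adjustment over the lists. List members were matched by symbol or synonym, 13899 of the gene symbols matching a RefSeq gene of Release 6, used for names and neighbours only; 349 shared a RefSeq gene with another. Counting the 2 lists added later, members shared with another list were 4 of 22 in the core clock list, 13 of 16 in circadian identity, 1 of 15 in the glial list and 0 in the photoreceptor, fat body and immune lists. A fold against a group without reads is a lower bound with 3 reads over the group as floor; with such genes at their bound or ratio, every list median kept its value.

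The other alternatives were no filter, a mean RPKM of at least 5, median-of-ratios scaling, the replicate number as a block, no trend and each library left out, where a lone library is assumed to vary like the other group. DESeq2 1.42.0, limma on log2 of RPKM plus 1 and scaling by library size only were added after the data were seen. Both count tests were tested on simulated data with the means and library sizes of these libraries. The changed genes were drawn only from genes with many reads, and each gene was simulated independently of the others. For this comparison over 7248 genes, edgeR recovered 10.4%, 89.6% and 100% of genes changed 4-fold, 16-fold and 64-fold, and DESeq2 38.8%, 95.5% and 100%. With no gene changed they called 1 and 19 genes. Recovery in the libraries themselves can be lower: Osi19, at least 608-fold lower, had an adjusted p of 0.213 in edgeR. A simulated shift of 1 on the log2 scale in the 30 mitochondrial genes gave an adjusted p of 2.04e-09 by camera, with 1 other list called. Figures and further tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.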

Results

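The libraries measured mRNA of dvpdf neurons from Drosophila melanogaster brains. The labels call 2 libraries control, and in the other 2 nonA, which encodes a nuclear RNA-binding protein of the NONO and SFPQ family, was targeted by RNA interference. Reads assigned to genes came to 8419248 and 9832771 in the control libraries and to 9673275 and 8558125 in the libraries labelled NonA RNAi, so that 3 reads corresponded to between 0.311 and 0.383 in normalised read counts scaled to library size (CPM). The number of genes with at least 1 read was 9098 and 9431 in the controls and 9512 and 9427 in the NonA RNAi libraries. The 10 most abundant genes took 7.8% and 5.5% of the gene reads in the controls, and 7.4% and 14.1% in the NonA RNAi libraries. Nothing in the labels says that replicates came from separate animals or dissections, so p-values measure only the spread between these libraries, which may be technical. Because the RNA was amplified, reads are not independent molecules, and counting intervals and floors cover counting error only. The counting is not stated to use strand, so values of genes that overlap another gene or lie antisense to it are uncertain.

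The first comparison asked whether the targeted gene was lower. It was not lower in both NonA RNAi libraries. The level of nonA was 263 and 252 CPM in control replicates 1 and 2, and 168 and 309 CPM in NonA RNAi replicates 1 and 2, from 2154, 2365, 1622 and 2424 reads. The means were 257 ± 7.72 CPM (SD, n = 2) and 239 ± 99.6 CPM (SD, n = 2), a log2 fold of -0.11 with a standard error of 0.5. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment this gave an adjusted p of 0.997 and a 95% interval of the log2 fold from -1.32 to 1.11. The groups of nonA values overlapped, and the label of NonA RNAi replicate 2 was not borne out by its nonA level. Whether reads of the RNA interference construct were counted as nonA was not tested. For this reason the libraries are named by their labels throughout, as the libraries labelled NonA RNAi, and every direction given for them rests on the label alone.

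Complexin, encoded by cpx, is a regulator of synaptic vesicle fusion and was singled out because work on NonA in clock neurons deals with it, so its choice was not independent of earlier findings. The level of cpx was 4170 and 2680 CPM in control replicates 1 and 2, and 1410 and 3470 CPM in NonA RNAi replicates 1 and 2. The means were 3420 ± 1050 CPM (SD, n = 2) and 2440 ± 1460 CPM (SD, n = 2), and the log2 fold was -0.49 with a standard error of 0.64. The adjusted p of edgeR was 0.993 and the 95% interval ran from -2.06 to 1.08, so the difference was smaller than the spread between replicates. Without NonA RNAi replicate 1 the log2 fold was 0.02, and it ranged from -1.32 to 0.02 over the libraries left out.

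The next comparison concerned the circadian clock. The transcripts of tim, vri, cwo and Pdp1 were higher in both libraries labelled NonA RNAi than in both controls, with log2 folds of 0.89, 0.84, 1 and 0.62 and standard errors of 0.56, 0.59, 0.51 and 0.58. tim, whose protein is the partner of PER in the repressor complex, was at 1680 and 868 CPM in the controls and at 2600 and 2110 CPM in the NonA RNAi libraries. The controls differed in the same order for vri (799 and 350 CPM), cwo (181 and 94.8 CPM) and Pdp1 (2110 and 1010 CPM). The separations of these genes may therefore not be independent of each other. Atx2, an RNA-binding factor in the translation of per, was at 530 and 516 CPM against 191 and 255 CPM, a log2 fold of -1.23 with a standard error of 0.46. The blue-light receptor gene cry was at 486 and 445 CPM against 688 and 546 CPM, and cyc at 36.9 and 36.6 CPM against 52.4 and 50.6 CPM. The transcripts of dco, slmb and mts were, like that of Atx2, lower in both NonA RNAi libraries than in both controls. In total 6 of the 22 clock genes lay above and 4 below both controls in this way. Over all genes the groups were apart for 31.9%, where chance gives 33.3% for either order together. None of these genes passed edgeR's test, with an adjusted p of 0.916 for Atx2 and 0.938 for cwo. Over the libraries left out, the log2 folds ranged from 0.46 to 1.44 for tim, 0.34 to 1.56 for vri, 0.57 to 1.54 for cwo and 0.16 to 1.25 for Pdp1.

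For the remaining clock genes the log2 folds lay between -0.61 and 0.68, with jet at the low end and CG17282 at the high end. Clk, the activator of the clock loop, was at 29.4 and 101 CPM in the controls and at 164 and 26.7 CPM in the NonA RNAi libraries, a spread within each group larger than the difference of the means. per was at 118 and 39.7 CPM against 143 and 65.4 CPM. Without single libraries the log2 fold of Clk ranged from -1.29 to 1.67 and that of per from -0.27 to 1.39. The kinase genes dco, sgg, CkIIalpha, CkIIbeta and nmo had log2 folds of -0.47, -0.08, 0.01, 0.14 and 0.18; CkIIalpha turned to -0.01 or -0.02 under other scalings between libraries. The phosphatase subunits tws, wdb and mts were at -0.22, -0.35 and -0.46, the ubiquitin ligase subunit slmb at -0.51, and CG42856 and CG4857 at -0.17 and 0.08. Of the 22 clock genes 13 were higher and 9 lower, 0 passed over all genes in edgeR (1 at an unadjusted p under 0.05), and 0 passed adjusted over the list alone.

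**Figure D1:**
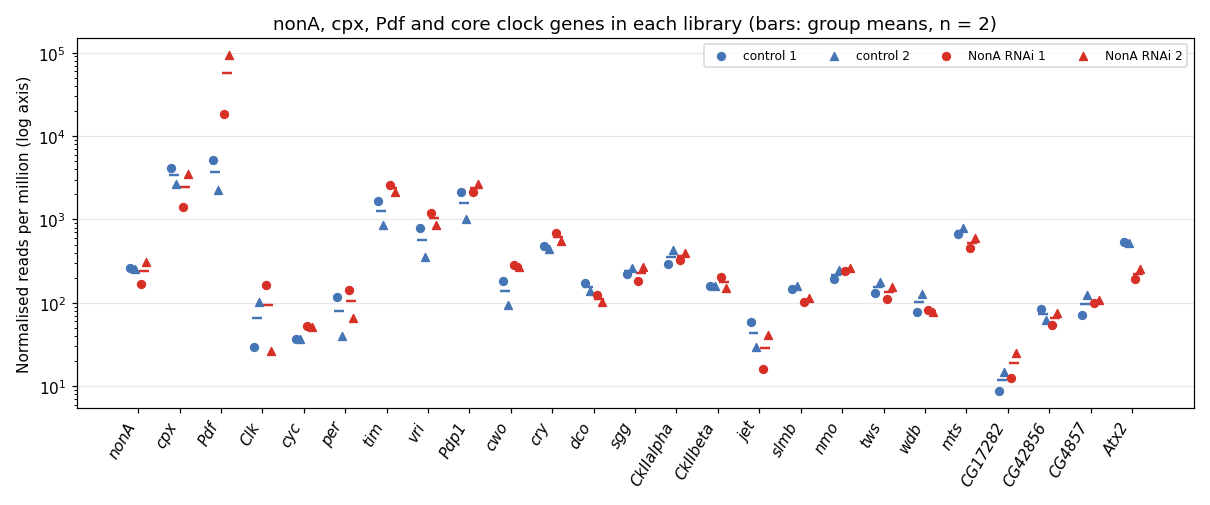
Normalised read counts in CPM (log axis) of nonA, cpx, Pdf and the core clock genes in each of the 4 libraries, with control libraries in blue, NonA RNAi libraries in red and bars at the group means (n = 2). The nonA values of the groups overlap, between 168 and 309 CPM, while the Pdf values lie at 5110 and 2260 CPM in the controls and at 18500 and 94500 CPM in the NonA RNAi libraries.

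Pdf, the gene of the circadian neuropeptide PDF, was 15.3-fold higher in the libraries labelled NonA RNAi. Its level was 5110 and 2260 CPM in the controls and 18500 and 94500 CPM in the NonA RNAi libraries, a log2 fold of 3.94 with a standard error of 1.03. NonA RNAi replicate 2 held 740916 Pdf reads, against 178335 in NonA RNAi replicate 1 and 41921 and 21229 in the controls. The adjusted p of edgeR was 0.798, so the difference did not pass the threshold of 0.05, while DESeq2 called it. The log2 fold was 2.29 without NonA RNAi replicate 2 and 1.68 with quantile normalization. In the same comparison the median log2 folds of glial, photoreceptor and fat body markers were -1.07, -0.27 and -3.27, and that of pan-neuronal genes 0.04. Whether the cells collected differed between the libraries, and with them the Pdf level, was not tested.

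Across the transcriptome, the largest separations of the groups were genes read almost wholly in 1 group. Higher in both libraries labelled NonA RNAi were mthl8, a receptor gene of the methuselah family, at 93.6 and 128 CPM against 0.366 and 0.213 CPM, and esg, a Snail-family transcription factor gene of stem and progenitor cells, at 115 and 121 CPM against 0.122 and 0 CPM. The ratio for esg was 2070 with a 95% counting interval of 372 to 81900. Lower were Osi19 of the Osiris family, with 1199 and 637 reads in the controls and 0 in both NonA RNAi libraries, and hug, the gene of the neuropeptide hugin, with 58659 and 8322 reads against 0 and 5. Ast-CC, an allatostatin peptide gene, was at 1850 and 780 CPM in the controls and at 24.6 and 27.3 CPM in the NonA RNAi libraries, a log2 fold of -5.66 with a standard error of 0.7.

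Of the 7248 genes tested, 0 passed an adjusted p under 0.05 in edgeR. At an unadjusted p under 0.05 there were 369, 107 higher and 262 lower in the libraries labelled NonA RNAi. Chance alone gives 362 if p-values are evenly spread. The smallest adjusted p was 0.0748, for mthl8 and esg. Split by replicate number, the same libraries gave 243 genes at an unadjusted p under 0.05. A crossed split, with control replicate 1 beside NonA RNAi replicate 2, gave 255. Both of these splits mix the labels, so a difference between the labels adds to the spread within their pairs. DESeq2, run on the same counts as an alternative added after the data were seen, called 132 genes, 23 higher and 109 lower, of which 56 had a library at 0. The groups did not overlap for 121 of the 132. Some of the others, such as fit and Dpt, were read in control replicate 1 alone. In the split by replicate number and the crossed split DESeq2 called 48 and 41 genes. On simulated counts for this comparison over the same 7248 genes, 29.4% of the 221 DESeq2 calls were genes made without a change, against 7.6% of the 144 calls of edgeR. Without control replicate 2 edgeR called 21 genes, 1 higher and 20 lower, and without the filter on low values 95, 13 higher and 82 lower. For a single gene, an exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333. Of the 82 genes named by rule besides nonA and cpx, 48 had a fold that moved by over 1.5 times when a single library was left out.

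Of the 10 higher genes with the smallest p among those with a mean of at least 10 RPKM in the higher group, 0 passed in edgeR and 6 in DESeq2. They also held Trh, the tryptophan hydroxylase gene of serotonin synthesis, at 286 and 137 CPM against 11.8 and 0.851 CPM, a log2 fold of 5.07 with a standard error of 1.24. The gustatory receptor gene Gr32a was at 125 and 22.8 CPM against 9.63 and 6.7 CPM, and the mismatch repair gene Pms2 at 280 and 67.3 CPM against 33.3 and 30.5 CPM. pch2 had a log2 fold of 2.04 with a standard error of 0.52. Alr was at 95.1 and 25.6 CPM against 6.22 and 12.8 CPM, and its log2 fold of 2.67 became 1.43 without NonA RNAi replicate 1. The cuticle protein gene Cpr60D had 207 and 65 reads against 0 in both controls, at least 91.3-fold higher with the floor of 3 reads taken over the group. retinin had 1909 and 23 reads against 0, at least 649-fold higher, and most of its reads came from NonA RNAi replicate 1.

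Of the 10 lower genes with the smallest p under the same limit, 0 passed in edgeR and 10 in DESeq2. They held the peptide gene Ccap, at 247 and 43.4 CPM in the controls against 1.97 and 3.44 CPM in the libraries labelled NonA RNAi, a log2 fold of -5.74 with a standard error of 1.02. The tetraspanin gene Tsp42Eh was at 182 and 73.7 CPM against 10.7 and 5.48 CPM, and the sarcoglycan gene Scgdelta at 397 and 235 CPM against 38.1 and 55.5 CPM. CG12836 had a log2 fold of -4.64 with a standard error of 0.84. With the floor of 3 reads over the group, Osi19 was at least 608-fold, CG7296 at least 309-fold and the pupal cuticle gene Pcp at least 284-fold lower. borr, a gene of the chromosomal passenger complex, had 787 and 107 reads against 2 and 0, a ratio of 444 with a 95% counting interval of 123 to 3670.

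**Figure D2:**
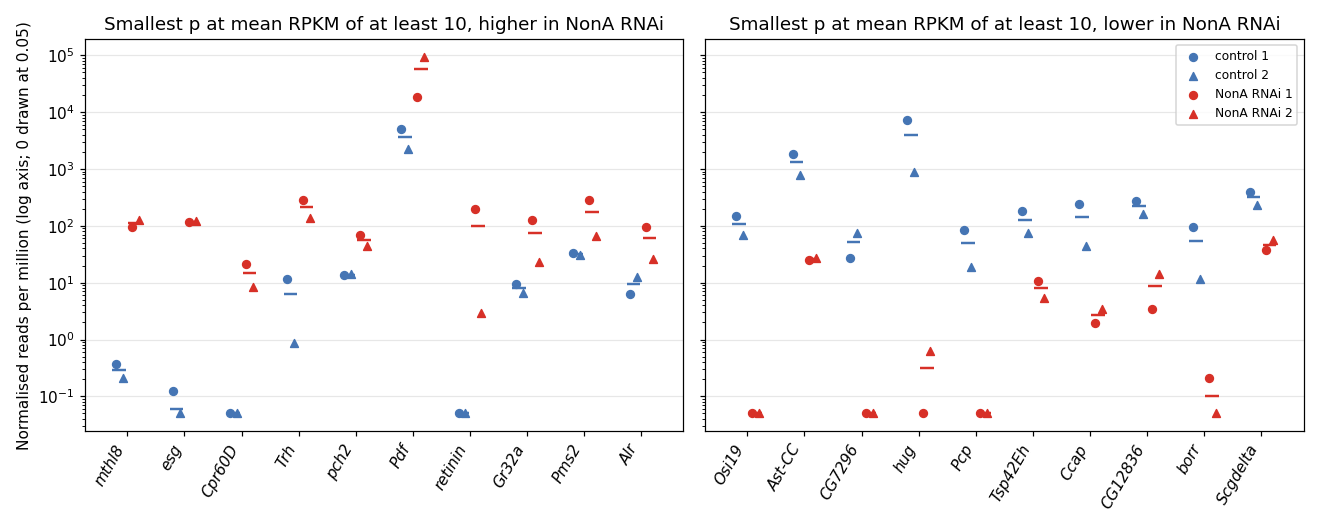
Normalised read counts in CPM (log axis, 0 drawn at 0.05) in each library of the 10 higher and 10 lower genes with the smallest p among those with separate groups and a mean of at least 10 RPKM in the higher group, with control libraries in blue, NonA RNAi libraries in red and bars at the group means (n = 2). The smallest adjusted p among them was 0.0748, so none passed edgeR's threshold of 0.05, and retinin shows a wide gap between the NonA RNAi libraries, at 198 and 2.93 CPM.

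The gene lists asked which pathways and cell types differed. In the libraries labelled NonA RNAi, 21 of 22 immune effector genes were lower, with a median log2 fold of -4.50, as were 12 of 14 fat body and hemocyte genes, with a median of -3.27. Of the glial genes 13 of 15 were lower, with a median of -1.07, and of the photoreceptor genes 8 of 9, with a median of -0.27. Of the genes of cytoplasmic ribosomal proteins 75 of 84 were higher, with a median log2 fold of 0.36. These lists passed camera of limma with a preset correlation of 0.01, at adjusted p = 1.2e-09, 4.58e-07, 0.0159, 0.00164 and 0.00281 in that order. Not a single list held with an estimated correlation, where each of the 16 lists had adjusted p = 0.936, or with fry's test for a change in 1 direction, where each had adjusted p = 0.898. Both NonA RNAi libraries lay below both controls for 7 immune, 4 fat body, 2 glial, 5 photoreceptor and 1 ribosomal protein genes, and above both for 0, 0, 1, 0 and 19; chance gives 33.3% for either order together. Each of the 5 calls was lost when a particular library was left out, as given for each list. With all libraries and the other settings that could be tested the calls held, but the medians ranged from -7.01 to -1.85 for immune, -3.74 to -1.1 for fat body, -1.09 to -0.4 for glial, -1.14 to -0.06 for photoreceptor and 0.33 to 0.5 for ribosomal protein genes. The photoreceptor median was -1.14 without a filter, where 21 members were measured.

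Among the immune effectors, the antimicrobial peptide gene Dro had 6016 and 31 reads in control replicates 1 and 2 and 0 in both NonA RNAi libraries. IM1 had 534 and 38 reads, IM4 2416 and 14 and IM2 549 and 28 in control replicates 1 and 2, against 0 in both NonA RNAi libraries for IM1 and IM4, and 0 and 3 for IM2. Of the fat body genes, the storage protein genes Lsp2 and Lsp1alpha had 219 and 71 reads and 1551 and 2 reads in the controls, against 0, and to was at 62.3 and 5.85 CPM against 1.35 and 1.02 CPM. fit had 3623 reads in control replicate 1 and 0 in each other library. In edgeR 0 members of either list passed over all genes and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 8 immune and 4 fat body genes. DESeq2 called 5 and 3, of which Dpt, TotA, TotC and fit were read in control replicate 1 alone. Without control replicate 1 the medians were 0.17 for the immune list and 0.01 for the fat body list, and neither list passed. These medians include genes without reads in the remaining libraries, such as fit, whose fitted log2 fold was then 0. The 4 immune genes named here stayed lower, at fitted values from -8.18 for IM1 to -3.92 for IM2. Lsp2 was at -9.08, Lsp1alpha at -4.02 and to at -2.29. These genes were named for their small p and rest on few reads in control replicate 2, so they do not stand for the lists.

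In the glial list CG2893 was at 97.6 and 140 CPM in the controls and 29.8 and 40.6 CPM in the NonA RNAi libraries, a log2 fold of -1.75 with a standard error of 0.46. nrv2, a sodium pump subunit gene, was at 569 and 1260 CPM against 72.7 and 400 CPM. CG32372 and CG16857 were highest in control replicate 2, at 1130 and 459 CPM, against 4.88 and 70.1 CPM in control replicate 1. Without control replicate 2 the median of the glial list was 0.43, without NonA RNAi replicate 1 it was -1.20, and neither passed. The photoreceptor list held the arrestin genes Arr1, at 14.4 and 93.4 CPM against 1.87 and 0.893 CPM, and Arr2, at 19.4 and 157 CPM against 5.29 and 9.57 CPM. The opsin gene Rh3 had a log2 fold of -3.98 with a standard error of 1.34. ninaE, another opsin gene, was at 145 and 56.2 CPM against 50.7 and 38.8 CPM, and its log2 fold of -1.17 became -0.33 without control replicate 1. Arr1 was the 1 photoreceptor gene that passed adjusted over the list alone, with an adjusted p of 0.0303 in edgeR, and 0 glial genes did; over all genes 0 members of either list passed (3 photoreceptor genes and 1 glial gene at an unadjusted p under 0.05), and DESeq2 called 3 and 1. Without NonA RNAi replicate 1 the photoreceptor median was -0.22 and the list did not pass.

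For the ribosomal proteins the single differences were small: RpL38 was at 519 and 842 CPM in the controls and 1200 and 1440 CPM in the libraries labelled NonA RNAi, and RpL29 and RpS4 had log2 folds of 0.77 and 0.82. RpL37b had 62 reads in NonA RNAi replicate 1 and 0 elsewhere. Over all genes and adjusted over the list alone, 0 of the 84 passed in edgeR, 0 had an unadjusted p under 0.05, and DESeq2 called 0. The median was 0.02 without control replicate 1 and 0.04 without NonA RNAi replicate 2, and the list did not pass in either case.

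Neuronal lists did not pass camera. For circadian neuron identity, 11 of 16 members were higher, with Pdf highest in fold, while CG14871, the gene of the peptide trissin, had 15885 and 7976 reads in the controls and 0 and 50 in the NonA RNAi libraries. The adjusted p was 0.693, and fry's test for changes in either direction, which does not compare a list with other genes, gave an adjusted p of 0.0476 for this list and did not pass for any other of the 16. Synaptic vesicle release had 20 of 33 members lower, and ion channels 12 of 22. In these, synj was at 120 and 154 CPM against 252 and 188 CPM, CG43073 had a log2 fold of -0.58, and the potassium channel gene Ir had 1.1. Irk2, another potassium channel gene, was at 121 and 1920 CPM in the controls against 34.2 and 156 CPM, and its log2 fold of -3.43 became -0.38 without control replicate 2. Of 15 transmitter genes 8 were lower, but Vmat, the vesicular monoamine transporter gene, was at 94.6 and 159 CPM against 345 and 615 CPM. Pan-neuronal genes were lower in 6 of 14, with jeb at a log2 fold of -0.93 and nrv3 at -0.37. The adjusted p of these 4 lists were 0.793, 0.693, 0.597 and 0.793.

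Of the other pathways, RNA-binding and splicing factors had 13 members higher and 13 lower at a median of 0.01, with Hrb87F at a log2 fold of -0.98 and U2af38 at 0.88. RNA interference machinery had 4 higher and 4 lower at a median of 0.20, with Dcr-1 at 11.5 and 6.6 CPM against 72.3 and 13.9 CPM and r2d2 at a log2 fold of 0.67. Heat shock and stress genes were lower in 10 of 18, with DnaJ-1 at -1.06, and ImpL3, lactate dehydrogenase, at 605 CPM in NonA RNAi replicate 1 but 6.25 CPM in NonA RNAi replicate 2. Neuronal activity-regulated genes were lower in 8 of 14, with CG11221 and h both at -1.37, and mitochondrial respiration genes in 17 of 30, with blw at -0.59 and CG4769 at -0.37. The adjusted p of these 5 lists by camera were 0.793, 0.597, 0.693, 0.597 and 0.693, and that of the core clock list was 0.772. In these 6 lists and the 5 neuronal ones, 0 members passed over all genes or adjusted over the list alone in edgeR, and at most 4 members of a list had an unadjusted p under 0.05. DESeq2 called 3 circadian identity genes and 2 transmitter genes, with Vmat in both, and 0 in the remaining lists. The RNA-binding median was -0.02 under other scalings between libraries, and with quantile normalization the heat shock and mitochondrial medians were 0.01 and 0.03. Without NonA RNAi replicate 1, circadian identity at a median of 0.74, transmitter genes at 0.67 and heat shock genes at -0.71 passed, and without NonA RNAi replicate 2 mitochondrial genes at -0.49 did.

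In 5 lists the median, the mean and the direction of the test differed in sign. Circadian identity had a median of 0.34 and a mean of -0.10, transmitter genes -0.03 and 0.46, and heat shock genes -0.16 and 0.11; the test pointed up, up and down. Pan-neuronal genes had 0.04 and -0.04 and RNA-binding genes 0.01 and -0.03, with the test pointing down in both. The muscle list had 4 measured members, under the 5 needed, and was not tested. Of these, Act57B had 1104 reads in NonA RNAi replicate 1 and 1 or 0 in each other library, and fln was at 14.4 and 35 CPM against 0.415 and 5.61 CPM.

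**Figure D3:**
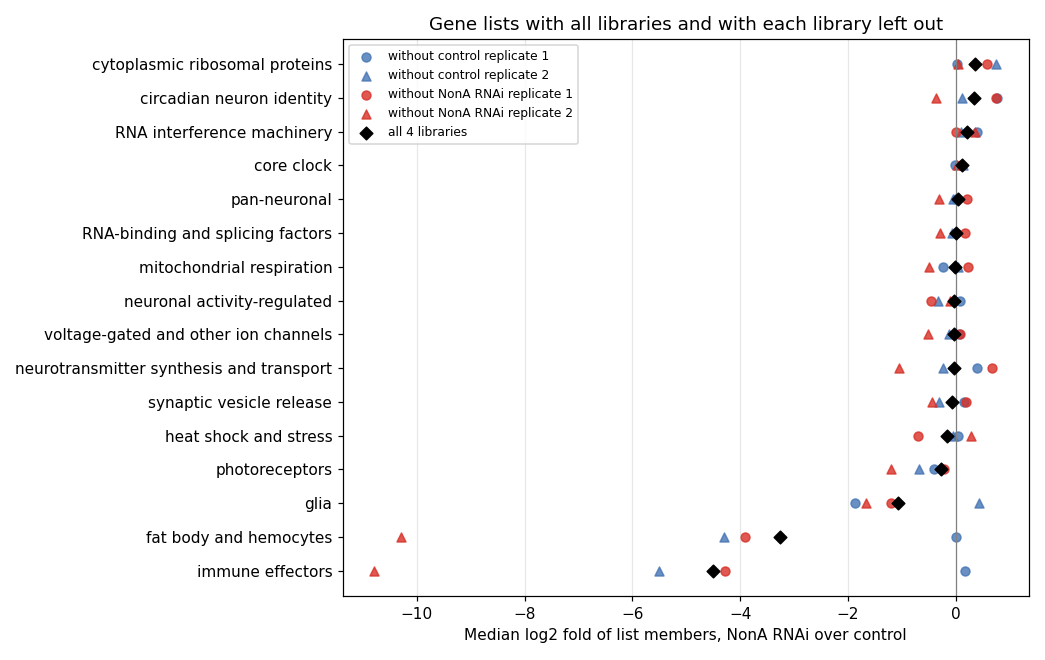
Median log2 fold of the members of each gene list, libraries labelled NonA RNAi over control, with all 4 libraries (black diamonds) and with each library left out (coloured points). The immune effector median moves from -4.50 to 0.17 without control replicate 1, and the glial median from -1.07 to 0.43 without control replicate 2. Medians include members without reads in the libraries kept, such as fit without control replicate 1, whose fitted log2 fold is then 0.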

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

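Of the alternatives, DESeq2, limma on log2 of RPKM plus 1 and scaling by library size only were chosen after the data were seen. The count of 0 genes by edgeR (369 at an unadjusted p under 0.05) became 95 without a filter and 132 with DESeq2, with 72 genes in both; leaving out single libraries gave 0 to 21, the highest without control replicate 2, and 16 of those 21 were DESeq2 calls. The cause was not tested. With the replicate number as a block the count was 0 (374 unadjusted) and no list fixed beforehand changed its call; deviations of same-numbered libraries correlated at -0.019, so the numbers were not taken as pairing. Of 82 named genes besides nonA and cpx, 26 passed with DESeq2, 26 without a filter and 10 without control replicate 2. The median log2 fold of all genes stayed within 0.1 of 0 in every setting. At this depth and spread, edgeR recovered 10.4% of simulated 4-fold changes, which were made only in genes with many reads.

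Apart from left-out libraries, values whose sign changed ended between -0.12 and 0.16. The mitochondrial median was 0.01 with a pseudocount of 0.1 or 5 and with limma on RPKM plus 1, 0.02 without a filter and 0.03 with quantile normalization, and the activity-regulated median was 0.01 with a pseudocount of 5. With a filter of 5 RPKM the medians were 0.07 for ion channels, 0 for RNA-binding genes, -0.12 for RNA interference machinery and 0.16 for heat shock genes, and the photoreceptor list had too few members for a test. CkIIalpha was at -0.02 with median-of-ratios scaling and DESeq2 and -0.01 with library size only, and the RNA-binding median was -0.02 in all 3. With quantile normalization CG42856 was at 0 and the heat shock median at 0.01.

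Leaving out each library in turn gave these ranges of log2 folds: nonA -0.65 to 0.27, cpx -1.32 to 0.02, Clk -1.29 to 1.67, per -0.27 to 1.39, sgg -0.41 to 0.16, CkIIalpha -0.24 to 0.29, CkIIbeta -0.08 to 0.3, wdb -0.66 to 0.02, CG42856 -0.46 to 0.08, CG4857 -0.27 to 0.51, nrv3 -1.07 to 0.08, CG32372 -6.07 to 1.84, CG16857 -2.58 to 0.1 and ImpL3 -2.22 to 4.33. Fitted values for fit, -14.91 to 0, and RpL37b, 0 to 8.85, rest on libraries without reads and are no bounds. List medians ranged over core clock -0.01 to 0.13, circadian identity -0.36 to 0.77, vesicle release -0.44 to 0.18, ion channels -0.52 to 0.07, transmitter genes -1.05 to 0.67, pan-neuronal -0.32 to 0.21, RNA-binding -0.3 to 0.17, glia -1.87 to 0.43, photoreceptors -1.21 to -0.22, fat body -10.29 to 0.01, immune -10.79 to 0.17, heat shock -0.71 to 0.29, activity-regulated -0.46 to 0.08, mitochondrial -0.49 to 0.22, ribosomal 0.02 to 0.75, neuropeptide precursors -3.36 to -0.37 and endoplasmic reticulum chaperones -0.43 to 1.23. The fat body, immune and ribosomal calls were lost without control replicate 1, the glial call without control replicate 2 or NonA RNAi replicate 1, the photoreceptor call without NonA RNAi replicate 1 and the ribosomal call also without NonA RNAi replicate 2; in each case the group then rested on a single library, and the cause was not tested further.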

Other observations

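Both lists described first, and every test below except that of fat body against glial genes between the controls, were chosen after the values were seen. Of the neuropeptide precursor genes 17 of 23 were lower in the libraries labelled NonA RNAi, with a median log2 fold of -1.38 and adjusted p = 7.46e-11 by camera. The list did not pass with an estimated correlation, at adjusted p = 0.245, or with fry, at adjusted p = 0.316 for 1 direction and 0.0898 for either. Markers of glia, photoreceptors and fat body were lower in the same comparison, with medians of -1.07, -0.27 and -3.27. The median ranged from -3.36 to -0.37 over the libraries left out, with -0.37 without control replicate 1, and from -2.96 to -0.73 over the other settings, and the camera call held in all of them. Besides hug, Ast-CC and Ccap, the allatostatin gene Ast-C was at 8230 and 4090 CPM in the controls against 220 and 1000 CPM, Ast at 1590 and 1960 CPM against 74.9 and 402 CPM, and Nplp2 at 832 and 102 CPM against 2.8 and 8.54 CPM. In 12 of the genes both NonA RNAi libraries lay below both controls, and in 1, Pdf, above; chance gives 33.3% for either order together. Over all genes 0 passed in edgeR (11 at an unadjusted p under 0.05), 8 were called by DESeq2, and 9 passed adjusted over the list alone, which is not independent evidence because some members prompted the list. itp, the gene of ion transport peptide, followed neither group, at 17500 and 1260 CPM in the controls and 935 and 16500 CPM in the NonA RNAi libraries.

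Of the endoplasmic reticulum chaperone genes 14 of 16 had a higher fitted level, with a median of 0.70. By camera the p was 0.0391 both before and after adjustment over the 2 added lists. It is therefore not a call over all lists. The adjusted p was 0.536 with an estimated correlation and 0.593 with fry. In NonA RNAi replicate 1, 14 of the 16 lay above both controls, and in NonA RNAi replicate 2, 12 lay below both. In total 0 passed in edgeR over all genes (1 at an unadjusted p under 0.05) or adjusted over the list alone. The values of Gp93 and Hsc70-3 were high in NonA RNAi replicate 1 and below both controls in replicate 2: Gp93 was at 391 and 327 CPM in the controls and at 6120 and 126 CPM in NonA RNAi replicates 1 and 2, and Hsc70-3 at 1510 and 1050 CPM against 6050 and 462 CPM. Both NonA RNAi libraries lay above both controls for TRAM, at 581 and 109 CPM against 95.8 and 58.9 CPM, and for Sec61beta. Without NonA RNAi replicate 1 the median was -0.43, in the other direction. The call was also lost with the replicate number as a block (median 0.33), without trend, with limma on RPKM at a pseudocount of 0.1, 1 or 5, and without either control; it held with quantile normalization (median 0.5). Genes with at least 100 reads in both libraries of 1 group and at most 3 in the other group together numbered 11. Those read in the libraries labelled NonA RNAi were esg, net and mwh, a wing hair polarity gene with 7854 and 1505 reads against 0 and 0; those read in the controls were Osi19, Osi4, Pcp, borr, conv, CG7296, CG10824 and CG14572. The hemocyte genes Hml and Sr-CI had 0 reads in NonA RNAi replicate 1, against 4012 and 2152 and 2823 and 842 reads in the controls and 1885 and 756 in NonA RNAi replicate 2. In RefSeq order mwh lies near Trh, with 2 genes between them.

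The level of nonA was not lower in both libraries labelled NonA RNAi. Counting error alone was argued against, since the pooled ratio of nonA reads was 0.902 with an exact 95% counting interval from 0.864 to 0.941. That interval pools NonA RNAi libraries at 168 and 309 CPM. It leaves out the spread between them and the amplification, so it does not exclude a halving hidden by these. Whether a control and a NonA RNAi library were swapped stays open: under the labels 11 genes were on in both libraries of a pair and off in the other pair, against at most 1 under the other splits, but the closest pair across genes was control 2 with NonA RNAi 2 (Pearson r 0.834, against 0.807 within NonA RNAi and 0.783 within control), and the splits are too few for a share under 0.05. A spread between libraries wide enough to hide a halving may account for it, as the interval of the log2 fold reached -1.32. A single wrong label, a knockdown that lowers protein without lowering the counted RNA, reads of the RNA interference construct counted as nonA, or RNA of cells outside the driver, stays open and was not tested.

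Fat body and immune genes were lower in the libraries labelled NonA RNAi. Whether these libraries held a single lower share of all cells that are not neurons stays open. Over control replicate 1 against control replicate 2 the fat body median was 3.64 and the glial median -1.13, a difference of 4.77. The lists thus differed between the controls, but no NonA RNAi library entered this test. Its permutation of list membership also counts genes that vary together as separate, so it cannot decide the question. In the labelled comparison the fat body and glial medians were both negative, at -3.27 and -1.07. Whether RNA of fat body or immune tissue entered control replicate 1 stays open: the immune median of 0.17 without that library restates the pattern and cannot decide it. Yp3 was at 1399 CPM there and at 6.38 CPM in control replicate 2, and fit had 3623 reads there and 0 in each other library, but Hml and Sr-CI were also read in control replicate 2 and NonA RNAi replicate 2. An immune response in the flies of that library and an effect of the knockdown on these genes stay open and were not tested.

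Genes lower in the libraries labelled NonA RNAi at an unadjusted p under 0.05 often lay next to each other, as Ast-C and Ast-CC do. Neighbours were taken among the 7017 tested genes with a known place, so untested genes can lie between them. The adjacent pairs included members of one family, such as IM2 with IM3, TotA with TotC and Tsp42Eg with Tsp42Eh. Random orders take no account of such families. Chance order was argued against, with 37 adjacent pairs against 9.07 in random orders, a ratio of 4.08 and a permutation p of 0.0001, the smallest that 10000 orders can give. The split by replicate number gave ratios of 3.18 and 2.88 in its 2 directions, and the crossed split 3.58 and 5.55. The ratio of 5.55 rested on 6 pairs against 1.08 in random orders. Neighbouring genes varying together in any split of these libraries is therefore a candidate explanation. An effect of the knockdown on neighbouring genes stays open as an addition to this.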
